A study of Macaca fascicularis and Macaca mulatta with 6 samples.

How the data were processed

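Peripheral blood mononuclear cells of 6 animals were measured, 1 library each: Mauritian cynomolgus macaques 1 (MHC genotype M1/M1, 7.3 years, male), 2 (M3/M3, 3.8 years, male), 3 (M2/M4, 11.5 years, female) and 4 (M6/M6, 12.1 years, female), and Indian rhesus macaques 1 (2.4 years, female) and 2 (12.4 years, female). Per the labels, the libraries were made with a 5′ version 2 droplet kit with a barcode of 16 nt and a UMI of 10 nt and sequenced with 29 and 289 cycles. Cynomolgus 1 and 2 share a batch, cynomolgus 3 and 4 share another, and each rhesus animal has its own. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.0 per the file headers and with Cell Ranger 2.1.1 per the submitters' notes, on Mmul_10. The lowest barcodes hold 500 UMIs. The other deposited files are feature names, barcodes and gene annotations.

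The 4 cynomolgus tables have the same 33960 features, reference symbols without allele names, and the allele annotations deposited with them do not match those tables. Allele counts were therefore made in the rhesus animals only, whose tables (40306 and 40328 features) hold 25 and 47 of the animal's own allele models in place of the reference classical MHC genes, 15 and 35 of them class I. In all, 33921 features are in every table. For rhesus 2 the genotype label names A019.02, B012.03 and B015.03, while the features are A1*019:11:01:01, B*012:01:01:01 and B*015:05:01:03; feature names are used throughout. Of 39 cynomolgus features absent from both rhesus tables, 18 without a descriptive name were counted as class I. A further 11 features, present in all tables, were counted as class I because the annotation describes them so. In the cynomolgus tables, reads of an animal's own alleles were counted on reference genes, and where unmatched reads went was not tested. DPB held 3636, 110560, 2251 and 48017 UMIs over all barcodes in cynomolgus 1 to 4, and DQB 52015, 1972, 1471 and 593. Single loci, and the DP and DQ part of the class II sums, may therefore depend on the genotype.

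Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, 63022 of 75955. The mitochondrial filter removed 0 barcodes in the cynomolgus libraries, which hold at most 0.0187% mitochondrial UMIs, and 2467 and 1234 in the rhesus libraries, which hold 8.41 and 7.01%. With so few mitochondrial UMIs counted, the 0 says nothing on the quality of the cynomolgus cells. Median UMIs per barcode were 5214, 4991, 4647 and 4615 in cynomolgus 1 to 4 and 9650 and 6993 in rhesus 1 and 2, with library totals of 55737854 to 174984301 UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5; because the automatic threshold marked from 2 to 581 barcodes per library, the highest scores were marked instead at 0.8% per 1000 barcodes, 669 to 1047 per library. That left 57696 cells. Barcodes under the cell filter (499, 742, 769, 510, 3406 and 3306) served as a background that holds low-count cells besides free RNA.

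Each library was clustered alone (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2) without MHC features or list genes that are not cell type markers. Clusters were named by fixed marker lists. A cluster took the name with the highest mean log2 fold over the library when at least 3 detected markers were raised and the lead was at least 0.2. CD4 and CD8 T clusters were set by the shares of cells with CD3D, CD3E, CD4, CD8A and CD8B, and mixed clusters were clustered again. The naming thresholds, the second clustering and the doublet rule were set after the clusters were seen, and the naming rule was revised 2 times on clusters and cell numbers, before any MHC value by type was computed: markers found in under 10% of cells were given no weight, and the lead was lowered from 0.5 because an NK-like cluster of cynomolgus 4 stayed unnamed. Marker lists, gene lists, comparisons, tests and most alternatives were fixed before the data were examined.

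UMIs were summed per animal and cell type where an animal had at least 30 cells, since cells are not replicates. Class I and class II (DR, DP, DQ) sums were compared as log2 CPM of all UMIs, with 1 added to the count, in B, CD8 T, NK and classical monocyte cells, each against CD4 T cells of the same animal, by an exact two-sided sign-flip permutation test adjusted by Benjamini and Hochberg over the 8 contrasts. Loci were compared in the same way, over 68 tests. Genes of 6 fixed lists (class I pathway, class II pathway, class I-like, interferon response, costimulation, handling stress; 91 genes, 83 in every table, 81 tested) were compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood) in 1 fit of 13435 genes over the 5 types with the animal as a block, at an adjusted p of 0.05 over all fitted genes. The biological coefficient of variation was 0.228. SEs were taken from the fold change and the F statistic. The lists were tested as sets with fry and camera (limma 3.58.1). MARCHF1, MR1, MICA, GBP1, GBP2, GBP5, LGALS9 and HSPA1B were absent from the tables under these symbols. Other genes were fitted to estimate the spread and are not reported, since the clusters were built on them.

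Named genes follow a fixed rule: the class I loci A, B, E, F, I and AG, the other class I features and the class II loci with at least 100 UMIs, per list and comparison up to 3 genes with the largest fold change past the threshold in each direction, and B2M, CD74, CIITA and NLRC5 throughout. Alleles are named from 5% of their locus or class, at most 10 per animal and class, with both members of each heterozygous pair; any further name is given as chosen afterwards. Shares of UMIs have exact binomial 95% intervals (Clopper and Pearson), which cover counting error only. Detection per cell was thinned to 1500 UMIs. A fold against a group at 0 uses a floor of 3 UMIs over the group.

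The gene test was tested on simulated data made from the same libraries. In each run a small random share of the genes was changed, up and down alike. In the real data most list genes were called in B cells and classical monocytes, so recovery and false share need not carry over. For B cells (12970 genes) it recovered 30.2% of 1.5-fold, 64.2% of 2-fold and 92.1% of 4-fold changes, and 8.40% of its calls were false. For CD8 T cells (13191 genes) these were 41.5, 65.2, 92.4 and 4.38%. For NK cells (13110 genes) they were 28.4, 67.7, 82.8 and 7.2%, and for classical monocytes (12742 genes) 36.9, 61.5, 90.6 and 8.27%. The sign-flip test passed 99.8% of 2000 draws of 6 differences of 1 with an SD of 0.3, and 2.9% of draws with no difference.

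Alternatives covered the cell filter, doublets, Leiden resolution, naming of each cell by its own marker score, scaling (CPM without MHC features, TMM, DESeq2 size factors, UMIs per cell), background subtraction, the pairing by animal, leaving out each animal, the DESeq2 1.42.0 Wald test, the low-count filter, fits of 2 types alone, the correlation in camera, thinning and averaging over cells. Those with no mitochondrial filter, the automatic doublet threshold, a naming lead of 0.5 and no unnamed class I features were chosen after seeing the data. Relative to CPM of all UMIs, other scalings moved every gene by the same amount in an animal. The mean log2 shift in B cells was -0.18 with TMM and -0.12 with DESeq2 size factors, in NK cells -0.19 and -0.15, and -0.23 per cell. In CD8 T cells it was -0.15 per cell, and in classical monocytes it was 0.26, 0.28 and 0.86. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Gene positions are from the deposited annotation. Raw reads were not used here.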

Results

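MHC class I and class II transcripts were compared between blood cell types of 6 macaques, 4 Mauritian cynomolgus and 2 Indian rhesus animals, whose mononuclear cells were profiled by droplet 5′ RNA sequencing. The classical MHC molecules present peptides to T cells; the labels give each animal's MHC genotype, and the question addressed here is how MHC loci and alleles differ in level between cell types. The 57696 kept cells held 12669 CD4 T, 6170 B, 11130 CD8 T, 5094 NK, 8479 classical monocyte and 5536 non-classical monocyte cells, and 6271 cells stayed unnamed. As a mean over animals (n = 6), CD4 T cells made up 21.8% of kept cells (SD 9.69), B cells 10.5% (SD 4.33), CD8 T cells 19.6% (SD 8.14), NK cells 8.50% (SD 6.95) and classical monocytes 14.6% (SD 3.74). The unnamed share was 8.17, 7.68, 5.49 and 28.9% in cynomolgus 1 to 4, and 11.3 and 6.38% in rhesus 1 and 2.

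Class I transcripts were highest in NK cells and lowest in classical monocytes. They made up 1.84% of all UMIs in NK cells (SD 0.415, n = 6), 1.48% in CD8 T cells (SD 0.659), 1.26% in B cells (SD 0.1797), 1.011% in CD4 T cells (SD 0.271) and 0.717% in classical monocytes (SD 0.279). The order was not the same in every animal: in cynomolgus 4, CD8 T cells held 2.62% and NK cells 2.55%. Non-classical monocytes differed from classical ones, with 1.59% (SD 0.324). They exceeded NK cells in cynomolgus 1 (1.82 and 1.78%) and rhesus 1 (1.68 and 1.62%). Myeloid dendritic cells held 1.05% (SD 0.414, n = 5), with 0.745 and 0.763% in rhesus 1 and 2, under the 0.874 and 0.916% of classical monocytes there. Within animals, the class I level in NK cells was above that in CD4 T cells by 0.88 on the log2 scale (SD 0.20, higher in 6 of 6 animals), and in CD8 T cells by 0.48 (SD 0.30, 6 of 6). In B cells the mean difference was 0.35 (SD 0.28, 6 of 6), with the smallest, 0.01, in cynomolgus 4; it no longer passed at 2000 UMIs, with cells named by their own marker score, with TMM or DESeq2 size factors, or without the 18 unnamed features. In classical monocytes the level was lower in 6 of 6 animals, with a mean difference of -0.57 (SD 0.43), but this reversed to 0.29 when UMIs per cell were compared with no depth scaling. It also no longer passed with TMM or DESeq2 size factors. Each of these 4 differences and the 4 of class II had an exact two-sided sign-flip p of 0.03125, the smallest that 6 animals allow, and an adjusted p of 0.03125 over the 8 contrasts.

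Class II transcripts of the DR, DP and DQ loci were concentrated in B cells, monocytes and dendritic cells. They made up 1.49% of UMIs in B cells (SD 0.171, n = 6), 0.885% in classical monocytes (SD 0.473), 0.62% in non-classical monocytes (SD 0.382) and 2.97% in myeloid dendritic cells (SD 0.719, n = 5). In CD4 T cells the share was 0.00465% (SD 0.00253), in CD8 T cells 0.0225% (SD 0.0150) and in NK cells 0.0224% (SD 0.0136). Against CD4 T cells the log2 difference was 8.57 in B cells (SD 1.03), 7.64 in classical monocytes (SD 0.80), 2.29 in NK cells (SD 0.88) and 1.91 in CD8 T cells (SD 0.90), each higher in 6 of 6 animals. The plot of class levels by cell type shows the values per animal. In CD8 T cells of cynomolgus 3 the difference was 0.16, against 1.83 to 2.49 in the other animals. Few DP UMIs were counted in that animal, 878 in its B cells against 21809 in those of cynomolgus 2. B cells of cynomolgus 1 held 345, with a CD8 T difference of 2.47. A counting gap and a difference of the animal itself cannot be told apart. The CD8 T result no longer passed with doublets kept, at 2000 UMIs, at Leiden resolution 0.5 or with the automatic doublet threshold.

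**Figure D1:**
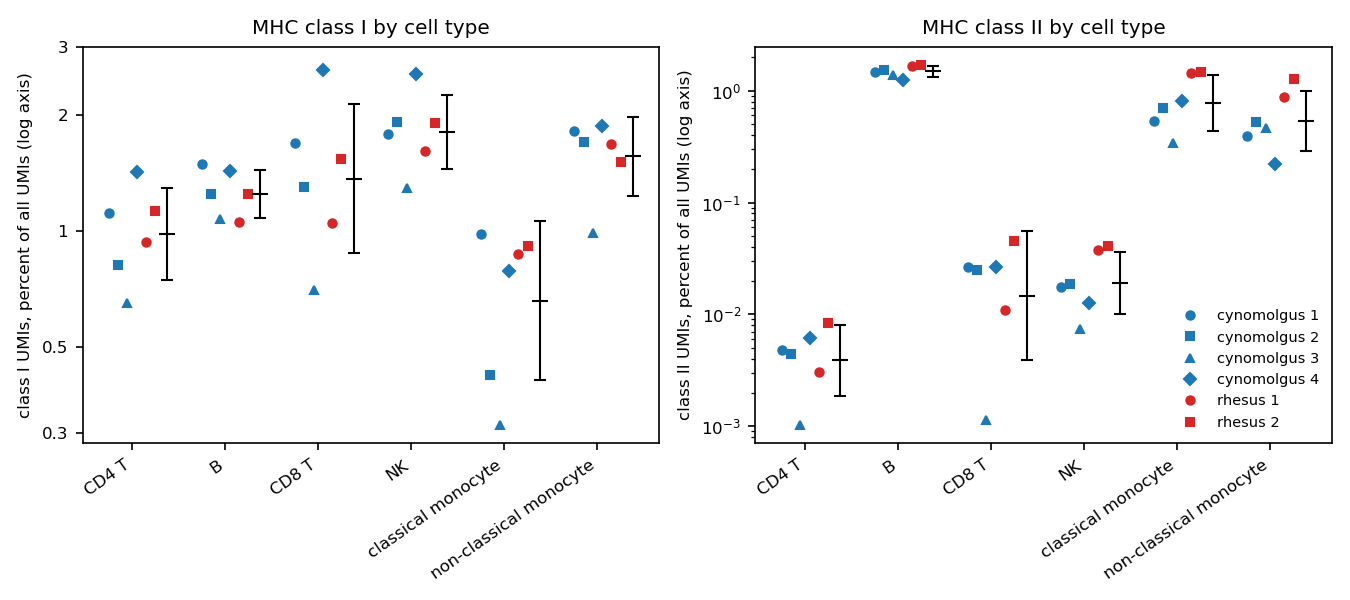
Class I (left) and class II (right) UMIs as a percent of all UMIs, on log axes, for 6 cell types; points are animals, and black bars give the geometric mean with 1 SD of the log2 values. The arithmetic means, which are not drawn, are 0.00465% in CD4 T and 1.49% in B cells for class II, and 0.717% in classical monocytes and 1.84% in NK cells for class I.

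Class II detection was read against barcodes under the cell filter, which hold low-count cells besides free RNA. At 1500 UMIs per cell, 99.9% of B cells and 94.9% of classical monocytes held a class II UMI (SD 4.68, n = 6), against 24.0% of NK cells (SD 14.8), 23.9% of CD8 T cells (SD 14.7) and 5.12% of CD4 T cells (SD 2.64). Without thinning the shares were 51.5% of NK, 45.8% of CD8 T and 15.6% of CD4 T cells, at median depths per animal of 3598 to 9736, 3836 to 11639 and 4314.5 to 10181 UMIs. Thinning left out 27 NK, 51 CD8 T and 40 CD4 T cells, besides 38 B cells and 33 classical monocytes. Class II UMIs averaged 0.315 per CD4 T cell against 0.918 per barcode under the cell filter, and the CD4 T level was at or under that background in 6 of 6 animals. The same held in 2 of 6 animals for CD8 T cells and in 1 for NK cells, and in 0 for B cells and classical monocytes.

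Among the class I loci read in all 6 animals, the NK difference was most even between animals at E. Its level (chromosome 4, 139406395 to 139409403, Mmul_10) was above that of CD4 T cells by 1.05 in NK cells (SD 0.13, n = 6) and by 0.48 in CD8 T cells (SD 0.35), and below it by a log2 difference of -1.05 in classical monocytes (SD 0.43), each in 6 of 6 animals. In UMIs per cell the monocyte difference of E was -0.19, with 3 animals higher and 3 lower. The A locus differed by 1.14 in NK cells (SD 0.51, 6 of 6) and by 0.38 in CD8 T cells (SD 0.21, 6 of 6). In classical monocytes A was lower in 5 of 6 animals (mean -0.41, SD 0.48), but higher by 0.45 in UMIs per cell. In B cells the differences were small, 0.15 for E and 0.08 for A, and both turned negative with TMM-scaled CPM. F (140510624 to 140513214) differed by 1.61 in NK cells (SD 1.05) and -1.85 in classical monocytes (SD 1.42), each in 5 of 6 animals. AG (140345860 to 140349192) was higher in NK cells by 1.17 (SD 0.76, 6 of 6); its mean difference in classical monocytes, -0.03, was positive under the other 3 scalings. The B locus, read in the 2 rhesus animals, was higher by 0.70 in NK, 0.32 in CD8 T and 0.22 in B cells, the last turning to -0.01 with TMM-scaled CPM. I, read in rhesus 2 alone, was higher by 0.78 in NK, 0.67 in CD8 T and 0.22 in B cells, and lower in classical monocytes (-0.31), where it was higher by 0.68 in UMIs per cell. Class I features outside the named loci, without the 18 unnamed ones, were higher in NK cells by 0.80 (SD 0.22, 6 of 6) and in CD8 T cells by 0.51 (SD 0.22, 6 of 6). The 18 unnamed features, in the 4 cynomolgus animals, were higher in NK cells by 0.86 (SD 0.31, 4 of 4), in B cells by 0.64 (SD 0.40, 4 of 4) and in CD8 T cells by 0.59 (SD 0.36, 4 of 4). In classical monocytes they were lower in 3 of 4 (mean -0.45, SD 0.52), but higher by 0.28 in UMIs per cell. No locus passed after adjustment over 68 exact two-sided tests (n = 6), where the smallest adjusted p was 0.0545 and the smallest possible raw p is 0.03125. Which paralog a class I read belongs to is uncertain, above all in the cynomolgus tables.

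The class II loci differed in how far they separated lymphocytes. DRA (chromosome 4, 137076488 to 137081619) was higher than in CD4 T cells by 9.41 in B cells and 8.42 in classical monocytes (log2, 6 of 6 animals each), but by only 0.43 in NK cells (3 of 6) and 0.57 in CD8 T cells (4 of 6). DPA and DPB were higher in NK cells by 3.15 and 3.34 (6 of 6 each), and in CD8 T cells by 2.26 (6 of 6) and 1.97 (5 of 6). In cynomolgus 1 and 3 these rest on 2 and 3 DP UMIs in NK and 2 and 1 in CD4 T cells, so that the count of 1 added sets much of their size; in the other 4 animals the NK differences ran from 1.35 to 4.51 for DPA and from 1.66 to 4.62 for DPB. DRB was higher by 8.19 in B cells, 7.58 in classical monocytes, 1.76 in CD8 T and 1.50 in NK cells. DQA was higher by 8.86 and DQB by 7.15 in B cells. DMA was higher by 8.11 in B cells, 7.42 in classical monocytes, 1.45 in NK and 1.09 in CD8 T cells, and DMB by 9.59 in B cells and 8.31 in classical monocytes. DOA was higher by 8.01 in B cells (SD 1.54) and 3.80 in classical monocytes (SD 1.34). The DP to DRA ratio was higher in NK cells than in barcodes under the cell filter in 6 of 6 animals, by 3.24 on the log2 scale (SD 1.37, lowest 1.99), and by 3.80 (SD 1.35) in the 4 animals with at least 20 DP UMIs in the barcodes under the filter, as the plot of that ratio by cell type shows. DOB (136716221 to 136720516) was higher in B cells by 7.75 (SD 3.67), with 9.04 to 11.4 in the cynomolgus and 3.59 and 2.66 in the rhesus animals. Its mean level in CD4 T cells was 0.131 CPM in the cynomolgus and 32.5 CPM in the rhesus animals. None of these locus differences passed after adjustment.

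**Figure D2:**
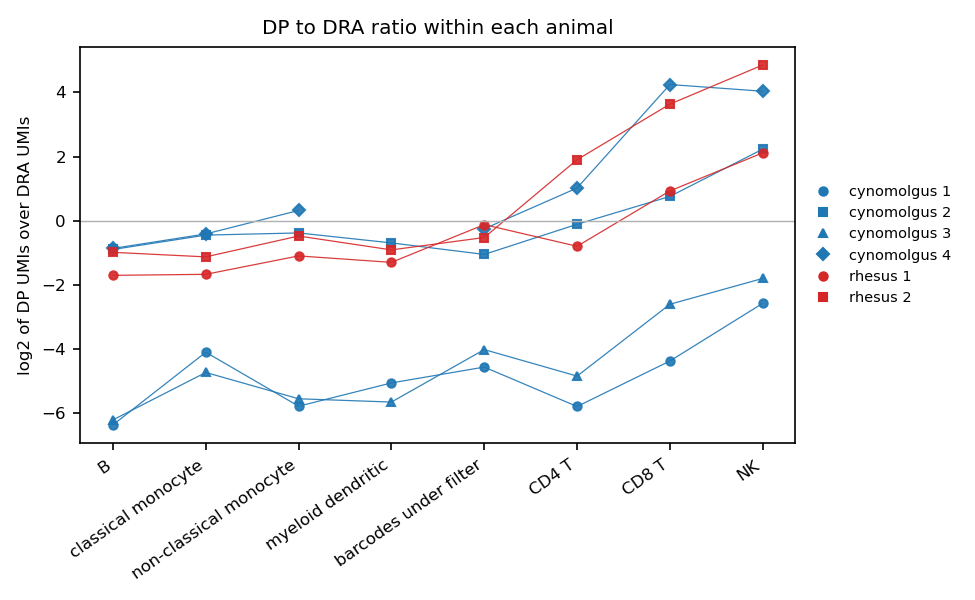
Log2 ratio of DPA and DPB UMIs to DRA UMIs (vertical axis) by cell type and in barcodes under the cell filter; points joined by lines are animals. NK cells lie above the barcodes under the filter by a mean of 3.24, with only 2 and 3 DP UMIs in NK cells of cynomolgus 1 and 3.

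In B cells, 39 of the 81 tested genes of the fixed lists rose and 14 fell against CD4 T cells (edgeR, adjusted over 13435 genes); adjusted over the list alone, 41 rose and 16 fell. The class II pathway set B cells apart, with 12 of its 15 genes higher and 1 lower. The largest log2 fold changes were in MAMU-DMB (9.65, SE 0.34), CIITA (9.51, SE 0.33) and MAMU-DOA (8.54, SE 0.51), with adjusted p of 6.39e-17, 4.76e-17 and 1.13e-12, while CD74 rose by 7.49 (SE 0.34). CIITA counted 12 UMIs in all CD4 T cells and 4725 in B cells. The protease gene CTSL fell, with a log2 fold change of -6.70 (SE 0.44). Class I pathway genes moved little and both ways, 4 up and 3 down of 17: TAP2 rose by 1.19 (SE 0.18), PSMB8 by 0.56 and PSMB9 by 0.51, while ERAP2 fell by 1.03, ERAP1 by 0.41 and PSME1 by 0.35. B2M was lower in 6 of 6 animals without passing (log2 fold change -0.36, SE 0.18, adjusted p 0.109), and NLRC5 did not pass either (-0.19, adjusted p 0.247). Of the costimulation genes 10 of 11 rose, with CD40 at 9.55 (SE 0.35), TNFSF9 at 3.87 and CD86 at 3.71. Of 22 interferon response genes 5 rose, among them CXCL10 (3.48, on 78 UMIs), MX2 (1.99) and MX1 (1.86), and 9 fell, among them OAS1 by 3.41, IFI44 by 3.25 and SOCS1 by 3.17. CD1D rose by 1.25. In the handling stress list 7 of 13 genes rose and 1 fell; NR4A1 rose by 5.76, EGR1 by 5.21 and DUSP1 by 1.87, and JUNB fell by 1.04.

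In classical monocytes, 47 of the 81 list genes rose and 12 fell against CD4 T cells, with the same 47 and 12 counts adjusted over the list alone. All 15 class II pathway genes passed, 12 higher and 3 lower. MAMU-DMB rose by 8.79 (SE 0.34, adjusted p 9.58e-17), CIITA by 8.60 (SE 0.33), MAMU-DMA by 7.79 (SE 0.28) and CD74 by 6.92 (SE 0.34). CTSL fell by 2.21 and RFXAP by 1.66, and MAMU-DOB fell by 3.35 (SE 1.30, lower in 4 of 6 animals), a direction that reversed under the DESeq2 Wald test. The large falls of DOB were in the rhesus animals. Its log2 CPM difference was -5.17 and -5.20 there, and -0.85, -0.79, 3.90 and 0.32 in cynomolgus 1 to 4. Of the class I pathway 3 genes rose and 5 fell. PSME2 rose by 1.22 (SE 0.14), PSMB10 by 0.87 and CANX by 0.55. ERAP2 fell by 1.40 (SE 0.13), TAP1 by 1.18 (SE 0.18), TAPBPL by 0.79 and NLRC5 by 0.58. B2M did not pass (log2 fold change -0.13, adjusted p 0.543); its mean was lower in the cynomolgus (-0.58) and higher in the rhesus animals (0.60). CD1D rose by 3.49 and FCGRT by 2.23.

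Of the interferon response genes 12 of 22 rose in classical monocytes and 3 fell. CXCL10 rose by 4.50 (SE 0.65), IFI44L by 4.16 and MX1 by 3.49 (SE 0.20), and SOCS1 fell by 5.21 (SE 0.38), OAS1 by 1.68 and ISG20 by 0.81. CD86 rose by 5.33 (SE 0.43), CD40 by 2.45 and ICOSLG by 1.90. CD70 had 0 UMIs in classical monocytes against 265 in CD4 T cells, which is at least 114-fold lower with a floor of 3 UMIs over the group. Handling stress genes rose in 10 of 13 cases, with EGR1 at 8.89, NR4A1 at 6.86 and FOSB at 6.53.

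In NK cells, 25 of the 81 list genes rose and 17 fell, with the same counts adjusted over the list alone. Of the 17 class I pathway genes 6 rose and 2 fell. PDIA3 rose by 0.70 (SE 0.10, adjusted p 4.23e-06), B2M by 0.54 (SE 0.18, adjusted p 0.0201, 6 of 6 animals) and CALR by 0.47, while ERAP2 fell by 0.53 and ERAP1 by 0.52. The class II pathway was split, 4 up and 4 down. MAMU-DMA rose by 1.17 (SE 0.28), CTSS by 0.77 and CD74 by 0.72 (SE 0.27, higher in 4 of 6 animals), but CTSL fell by 6.65, CTSH by 4.21 and LGMN by 2.90. CIITA, with 5 UMIs in all NK cells, did not pass (log2 fold change 0.24, adjusted p 0.867), nor did NLRC5 (0.03). MICB rose by 1.63, and CD1D fell by 1.73 and FCGRT by 1.69. IFI44L rose by 1.86, IFI6 by 1.80 (SE 0.26) and IFIT1 by 1.73, and SOCS1 fell by 2.01. TNFSF4 rose by 1.73, PDCD1LG2 by 1.45 and CD58 by 1.16, and CD86 fell by 3.38 and ICOSLG by 1.95. HSPA1A rose by 1.67 and IER2 by 0.90, and JUNB fell by 3.47, FOS by 2.79 and JUN by 2.28.

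CD8 T cells differed least from CD4 T cells: 5 of the 81 list genes rose and 3 fell, also when adjusted over the list alone. The 8 called genes became 20 in a fit of this pair of types alone and 13 with the DESeq2 Wald test. MAMU-DOA rose by 2.87 (SE 0.65, on 72 UMIs), CD74 by 1.30 (SE 0.27, adjusted p 0.00163), MAMU-DMA by 1.13 (SE 0.25), TNFSF4 by 1.07 and PDIA3 by 0.40. CTSL fell by 4.91 (SE 0.35), CTSH by 1.56 and RSAD2 by 1.62. B2M (0.43, adjusted p 0.147), NLRC5 (0.23) and CIITA (1.12, adjusted p 0.254, on 21 UMIs) did not pass. Per-gene values of the pathway lists are in the plot of pathway genes.

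**Figure D3:**
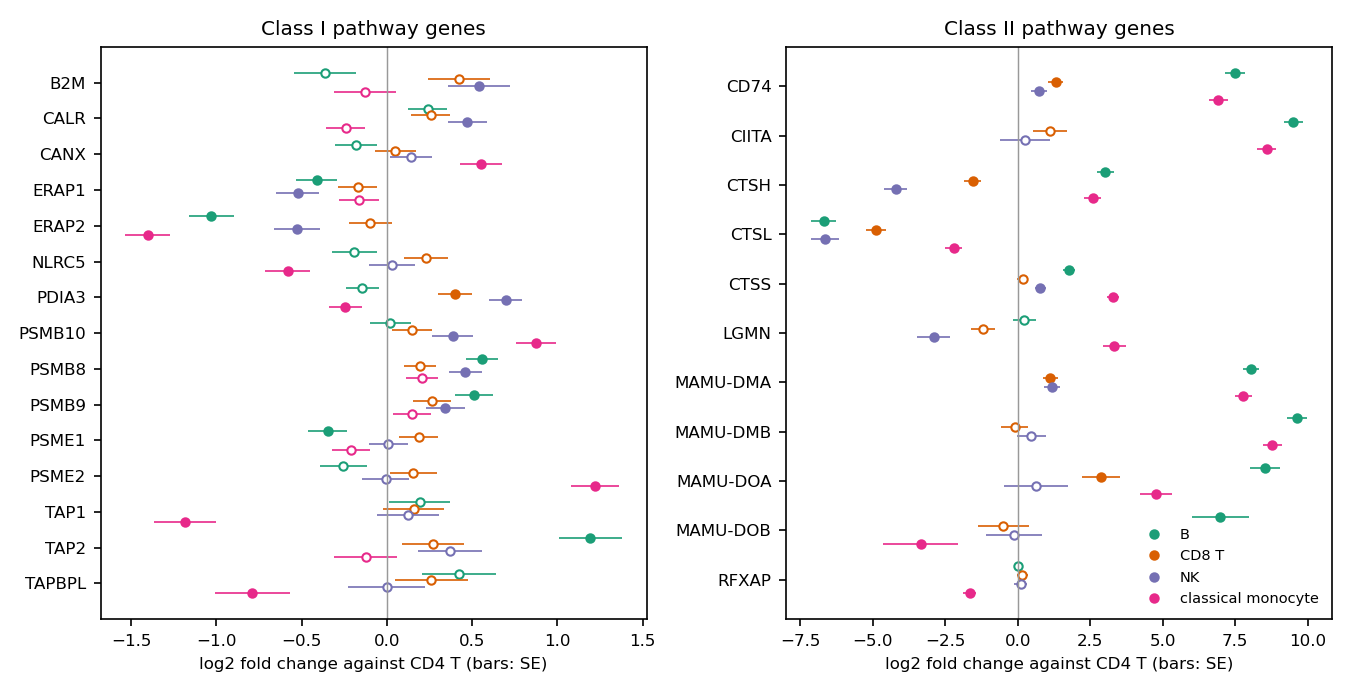
Log2 fold change against CD4 T cells (horizontal axis, bars 1 SE) of class I pathway genes (left) and class II pathway genes (right) in B, CD8 T, NK and classical monocyte cells; filled points passed an adjusted p of 0.05 and open points did not. CIITA lies at 9.51 in B cells and 8.60 in classical monocytes, while TAP1 lies at -1.18 in classical monocytes.

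As sets, the class II pathway genes ranked above the other genes in B cells (camera, preset correlation, adjusted p 1.41e-12) and in classical monocytes (6.42e-06), and both held with an estimated correlation (0.00234 and 0.0303). The preset calls for costimulation genes in B cells (0.000285), class I pathway genes in CD8 T cells (0.0403) and handling stress genes in classical monocytes (0.000434) did not hold with an estimated correlation. These values were adjusted over 24 set tests, and the remaining sets gave 0.0525 to 0.928. By fry, which tests the set's own genes and not against others, the genes moved on balance upward in both class II pathway cases, with adjusted p of 1.84e-15 and 2.67e-15. Other sets with a fry adjusted p under 0.05 moved on balance up in classical monocytes, namely handling stress (3.88e-11), class I-like (1.37e-08), costimulation (1.82e-05) and interferon response genes (0.000786). In B cells costimulation (1.14e-09), handling stress (0.000155) and class I-like genes (0.0308) moved up and interferon response genes down (0.0383), and in NK cells class I-like genes moved down (0.00530). Against other genes, the interferon response sets did not pass by camera with either correlation (0.406 and 0.913 in B cells, 0.442 and 0.913 in classical monocytes). Median, mean and test differed in sign for class I pathway genes in B cells (median -0.14, mean 0.02, test down), class II pathway genes in CD8 T cells (0.16, -0.09, down) and in NK cells (0.12, -0.68, down). The same was true of class I-like genes in CD8 T cells (-0.32, 0.08, down) and of costimulation genes in NK cells (0.10, -0.15, up).

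In the 2 rhesus animals, whose own alleles were counted, some class I transcripts were found almost only in myeloid cells. Under a rule set after the values were seen, 1 allele of rhesus 1 and 6 of rhesus 2 were at least 10 times higher in classical monocytes than in CD4 T, B, CD8 T and NK cells. B*134:03:01:01 of rhesus 1 made up 14.2% of class I UMIs in classical monocytes but 0.0197% in CD4 T, 0.0207% in B, 0.0217% in CD8 T and 0.0159% in NK cells. That is 1240 CPM in classical monocytes, on 49436 UMIs, against 1.84 CPM in CD4 T cells and 46.5 CPM in barcodes under the cell filter. B*098:08:01:01 of rhesus 2 made up 13.0% in classical monocytes (1190 CPM, 38790 UMIs) and 1.31 CPM in CD4 T, 1.78 CPM in B, 1.68 CPM in CD8 T and 0.978 CPM in NK cells. B*098:10:01:01 of rhesus 2, named after its values were seen, made up 4.44% in classical monocytes (407 CPM) and stayed under 0.445 CPM in those 4 lymphocyte types. Non-classical monocytes held 285 CPM of B*134:03:01:01 and 264 CPM of B*098:08:01:01, and myeloid dendritic cells 688 and 387 CPM. Which of several close B paralogs a read belongs to is uncertain, and each allele was counted in 1 animal, so that no replicate error can be given.

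**Figure D4:**
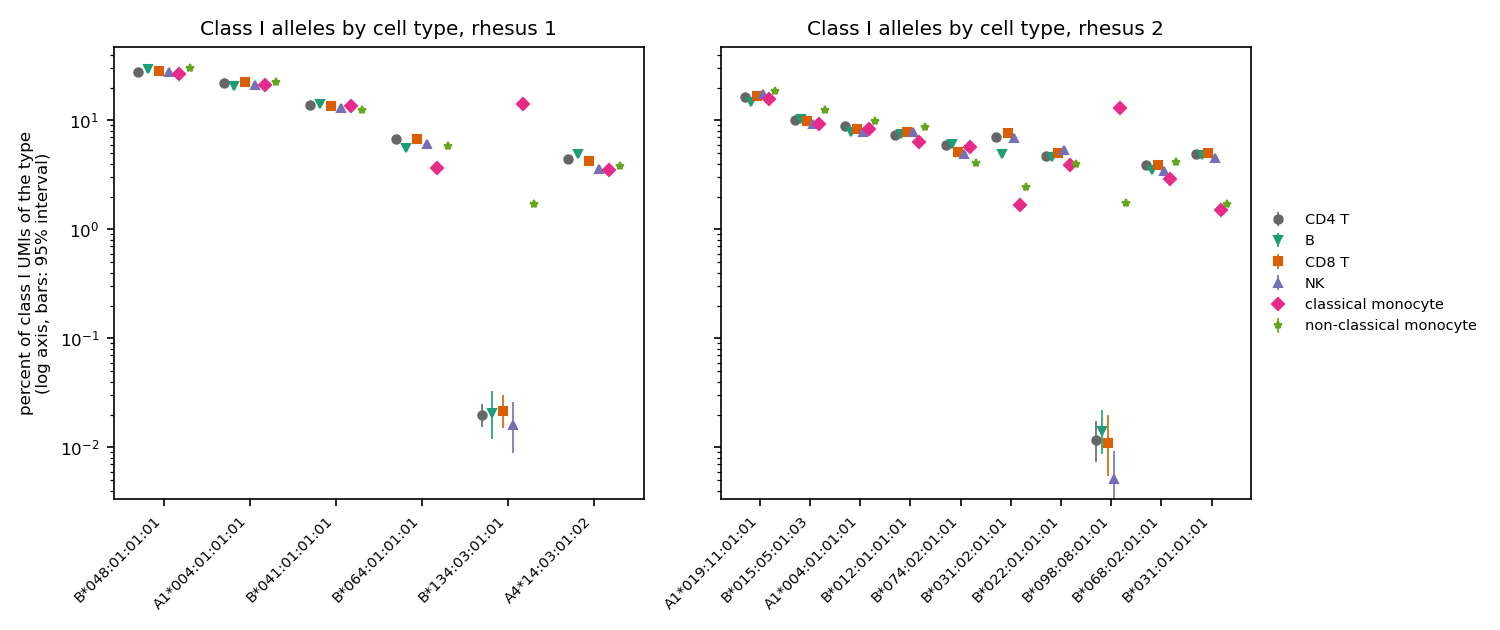
Percent of the class I UMIs of a cell type (log axis, bars 95% exact interval) from each named class I allele of rhesus 1 (left) and rhesus 2 (right); symbols are cell types. B*134:03:01:01 reaches 14.2% and B*098:08:01:01 13.0% in classical monocytes and each lies under 0.03% in CD4 T, B, CD8 T and NK cells.

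The order of class I alleles was similar among lymphocyte types, with exceptions. B*053:02:01:01 of rhesus 2, named after its values were seen, made up 3.02% of class I UMIs in B cells and 0.292% in CD4 T cells. In rhesus 1, B*048:01:01:01 led with 27.7% of class I UMIs over all kept cells, followed by A1*004:01:01:01 (21.8%), B*041:01:01:01 (13.5%), B*064:01:01:01 (5.62%), B*134:03:01:01 (4.06%) and A4*14:03:01:02 (4.0%). In rhesus 2, A1*019:11:01:01 led with 16.6%, followed by B*015:05:01:03 (10.2%), A1*004:01:01:01 (8.57%), B*012:01:01:01 (7.40%), B*074:02:01:01 (5.28%), B*031:02:01:01 (4.52%) and B*022:01:01:01 (4.47%). B*098:08:01:01 (3.64%), B*068:02:01:01 (3.53%) and B*031:01:01:01 (3.41%) came next. The genotype label of rhesus 1 gives A004.01/A004.01 and B048.01/B048.01, and that of rhesus 2 A004.01/A019.02 and B012.03/B015.03. Allele shares of the 2 animals may therefore rest on unlike copy numbers. As a mean over cells the leading alleles stayed the same, but B*134:03:01:01 took 2.22% and B*098:08:01:01 2.97%. The exact 95% intervals for B*048:01:01:01 (27.6 to 27.8%) and A1*019:11:01:01 (16.6 to 16.7%) cover counting error only. Across alleles, which are not independent replicates, Spearman's rho between CD4 T, B, CD8 T and NK cells was at least 0.955 in rhesus 1 (11 alleles) and 0.979 in rhesus 2 (30 alleles). Between classical monocytes and those types it was 0.718 to 0.782 and 0.584 to 0.604. B*031:02:01:01 made up 1.66% of class I in classical monocytes against 4.94 to 7.69% in the 4 lymphocyte types.

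The A locus took 35.03% of A and B UMIs in CD4 T cells (SD 0.345, n = 2 rhesus animals), 34.9% in CD8 T, 35.2% in NK, 32.6% in B and 30.6% in classical monocytes. The difference to CD4 T cells was -2.48 percentage points in B cells (-1.97 and -2.99) and -4.44 in classical monocytes (-4.99 and -3.90). It was -0.127 in CD8 T and 0.193 in NK cells, with the 2 animals apart in sign. With 2 animals the smallest exact two-sided p is 0.5, so that none of these could pass; B and classical monocytes both had 0.5. In classical monocytes, alleles at least 10 times higher there than in the 4 lymphocyte types, all of the B locus, made up 14.2% of class I UMIs in rhesus 1 and 19.98% in rhesus 2.

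The class II alleles of rhesus 1 were led by DRB5*03:01:01:01 (12.02% of class II UMIs), DRB*W004:01:01:01 (11.3%) and DPB1*07:01 (10.8%), followed by DRB*W003:03:01:01 (5.14%), DPA1*02:02:01:01 (4.38%), DQB1*18:02:01:01 (4.17%) and DRB1*04:06:01:01 (2.78%). Those of rhesus 2 were led by DRB*W002:05 (8.56%), DRB1*03:09:01:01 (8.24%), DRB1*10:07:01:01 (7.51%), DPB1*15:01 (7.01%), DPB1*07:01 (6.09%), DQA1*01:04:01:01 (5.24%) and DRB1*03:03:01:01 (4.67%). These orders hold for summed UMIs, most of which come from cells rich in class II. As a mean over cells, DQB1*18:02:01:01 led in rhesus 1 with 19.1% and DPB1*15:01 in rhesus 2 with 26.6%.

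The balance within some heterozygous class II pairs differed by cell type, and that of the only class I pair differed less. In rhesus 2, A1*004:01:01:01 took 34.0% of the UMIs of it and A1*019:11:01:01 over all kept cells, and from 31.1% in NK to 35.1% in CD4 T cells over the 5 compared types. A further A1 feature of this animal, A1*003:21:01:01N (chosen afterwards), held 4.16% of A UMIs and was left out of the pair. DPB1*07:01 took 45.1% of the UMIs of it and DPB1*15:01 in B cells and 47.98% in classical monocytes, but 15.4% in NK cells (exact 95% interval 14.2 to 16.7%), 15.2% in CD8 T and 9.40% in CD4 T cells. Barcodes under the cell filter held 45.8% (41.4 to 50.3%). In rhesus 1, DQB1*18:01:01:01 took 32.2% of the UMIs of it and DQB1*18:02:01:01 in B cells and 30.6% in classical monocytes, against 1.26% in NK (0.606 to 2.31%), 7.39% in CD8 T and 3.07% in CD4 T cells and 25.5% in barcodes under the filter (19.5 to 32.3%). DQA1*23:01:01:01 of the same animal took 44.7% of the UMIs of it and DQA1*26:01:01:01 in B cells and 93.8% in NK cells, on few UMIs. DRB*W004:01:01:01 took 46.9% of the UMIs of it and DRB5*03:01:01:01 in B cells, 49.7% in classical monocytes and 53.6% in NK cells. These 2 carry different DRB names among several DRB features of rhesus 1, so they may be 2 genes and not a heterozygous pair. In rhesus 2, DPA1*02:01:01:01 took 62.8% against DPA1*02:02:01:01 in B cells, 58.4% in classical monocytes and 49.9% in NK cells. DQA1*01:04:01:01 took 69.8, 84.5 and 79.6% in these types, and DQB1*06:01:01:01 took 58.1, 70.8 and 63.6%, the last on 22 UMIs.

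**Figure D5:**
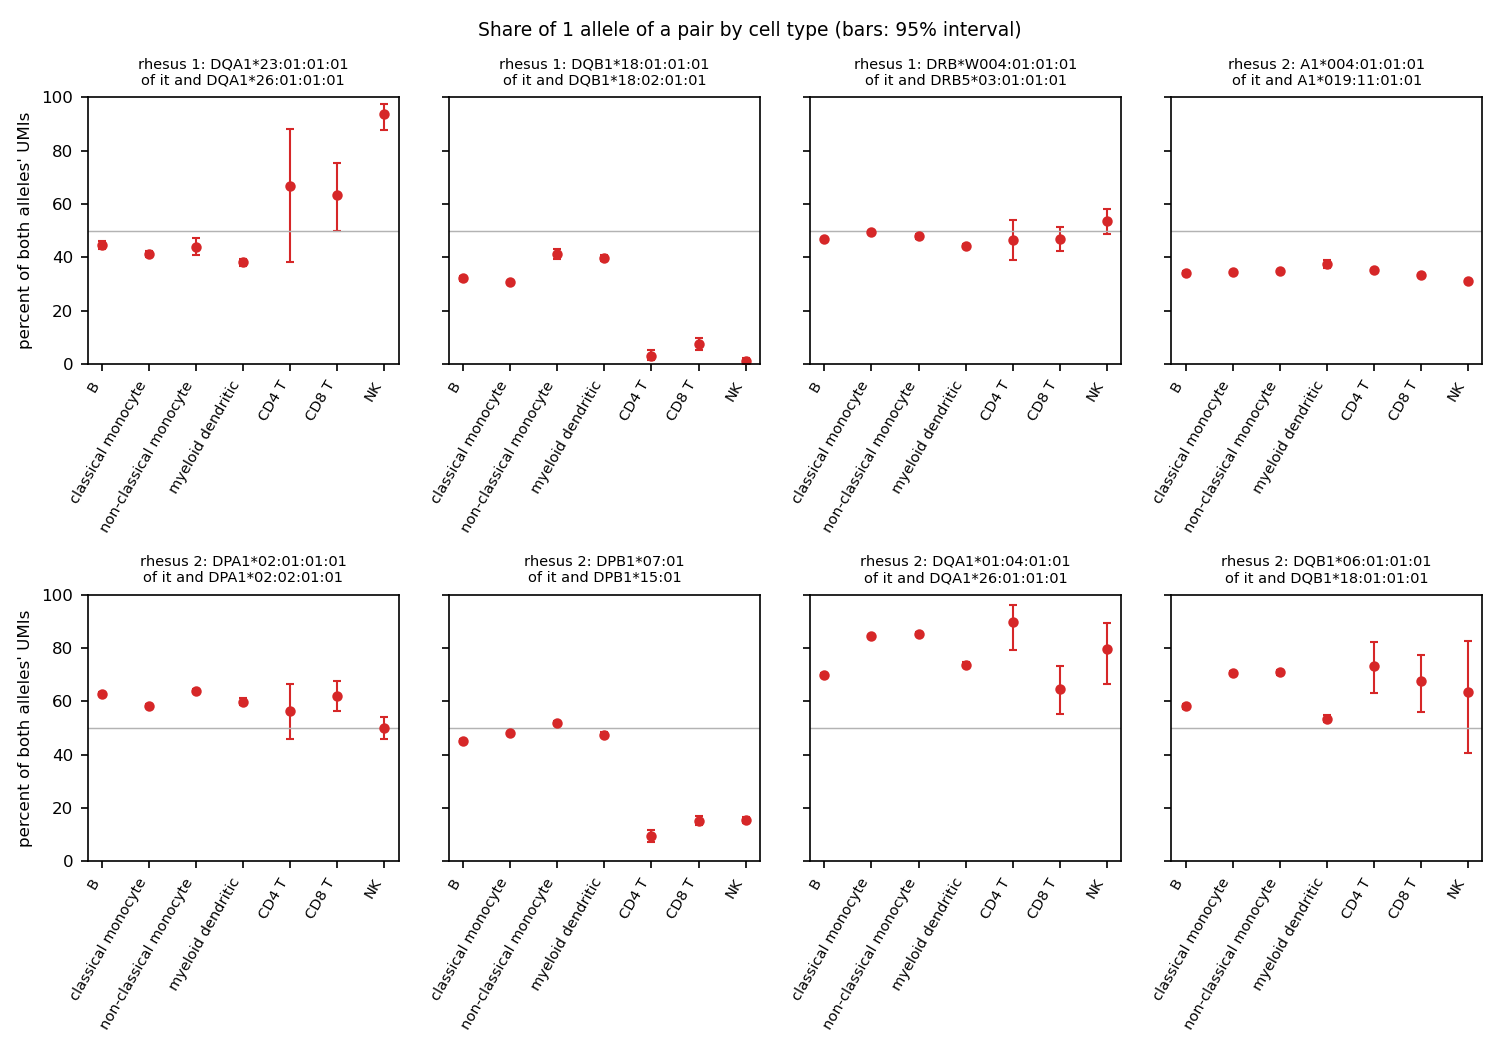
Percent of the UMIs of both alleles that came from the first (vertical axis, bars 95% exact interval) in 7 cell types for 8 pairs of the rhesus animals. The DRB pair of rhesus 1 may be 2 genes, and the others are heterozygous pairs. DPB1*07:01 lies at 45.1% in B cells and 15.4% in NK cells of rhesus 2, and DQB1*18:01:01:01 at 32.2 and 1.26% in rhesus 1.

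Both alleles of a pair were seen in the same cells about as often as independent detection gives. At 1500 UMIs, both A1 alleles of rhesus 2 were found in 69.7% of B cells, against 68.8% if independent, in 68.9% of CD4 T (69.0%), 77.9% of CD8 T (78.2%), 85.8% of NK (85.8%) and 56.9% of classical monocytes (55.4%). In B cells of rhesus 2 the shares with both alleles were 58.5% for DPB1 (58.1% if independent), 25.9% for DPA1 (24.2%), 32.3% for DQA1 (30.6%) and 36.0% for DQB1 (34.4%). In B cells of rhesus 1 they were 86.5% for the DRB pair (85.6%), 30.7% for DQB1 (29.4%) and 11.1% for DQA1 (9.93%). The DRB pair may be 2 genes and not 2 alleles of 1 gene.

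Between the species, the class II level in classical monocytes was higher in the rhesus animals by 1.36 (log2) and in NK cells by 1.56, each with an exact two-sided p of 0.0667, the smallest that 4 against 2 animals allow. In B cells it differed by 0.26, in CD4 T cells by 0.57 and in CD8 T cells by 0.90, and the last 2 changed sign when single animals were left out. Class I differed by 0.66 in classical monocytes (exact p 0.267), 0.10 in CD4 T, -0.18 in B, -0.16 in CD8 T and -0.07 in NK cells. Without the 18 unnamed features, which only the cynomolgus tables hold, these became 2.23, 1.13, 1.13, 0.88 and 0.89, so that B, CD8 T and NK cells changed direction. Species, batch, depth, the annotation used for counting and the reach of the mitochondrial filter all changed together, so that these cannot be told apart.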

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

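The tests on other splits of the libraries in B cells, on DP to DRA ratios, on allele shares and on class I in classical monocytes were chosen after the results were seen; the others were fixed before.

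A gap test was run in 296 groups of 4 to 6 animals and singled out 22 values that lay far from the rest; chance alone gives about 1 in 20 groups. Among within-animal log2 differences to CD4 T cells, class II in CD8 T cells of cynomolgus 3 stood apart at 0.16 (others 1.83 to 2.49). So did DRB in B cells of cynomolgus 4 at 4.90 (8.10 to 9.70) and DMA in NK cells of cynomolgus 3 at 3.02 (0.98 to 1.24). Few DP UMIs were counted in cynomolgus 3, so its class II value may reflect a counting gap. Of the named genes, CD1D in B cells of cynomolgus 1 lay at 1.64 (0.76 to 1.08), CD70 in classical monocytes of cynomolgus 3 at -0.14 (-2.75 to -1.81) and FOSB in classical monocytes of cynomolgus 4 at 3.33 (5.82 to 7.21). CD70 had 0 UMIs in classical monocytes of all 6 animals, so its value reflects the CD4 T counts and the small count added. B2M in classical monocytes went in opposite directions in the species, with a mean of -0.58 in the 4 cynomolgus and 0.60 in the 2 rhesus animals, a difference of 1.18 that was not tested.

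Levels in log2 CPM that lay far from the other cynomolgus animals came from cynomolgus 1, 3 and 4. In cynomolgus 3, class II in CD8 T cells was 3.53 (others 7.96 to 8.06), class I in non-classical monocytes 13.27 (14.05 to 14.19), A in CD8 T cells 8.74 (9.58 to 9.69) and DRA in CD4 T cells 2.33 (3.83 to 3.95). DMA was 1.22 in its CD4 T cells (1.71 to 1.73) and 4.24 in its NK cells (2.87 to 2.95), and MICB was 2.07 in its NK cells (0.79 to 0.95); these 118 NK cells held 8 DMA UMIs and 1 MICB UMI, too few to read as a level. In cynomolgus 4, AG was 13.26 in CD8 T cells (6.52 to 7.39) and 11.30 in classical monocytes (6.49 to 7.04), DPA 10.69 in B cells (3.93 to 4.55) and 6.05 in CD8 T cells (-1.09 to -0.64), and DRB 9.07 in B cells (at least 11.74). In cynomolgus 1, DQB was 11.30 in B cells (4.87 to 5.59) and 9.59 in classical monocytes (4.32 to 4.89). Each cynomolgus animal has another MHC genotype, read against the same reference symbols. The platelet share was 2.58% in cynomolgus 2 (0.507 to 1.19 elsewhere), and the unnamed share 28.9% in cynomolgus 4 (5.49 to 11.3).

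The counts of list genes were set against 100 splits of the 12 libraries of each pair of types, each fitted alone. In B cells 1 split, the real one, gave as many as the real 54 (highest other 0), in NK cells 1 (real 43, highest other 24) and in classical monocytes 1 (real 54, highest other 37). In CD8 T cells 2 splits reached the real 20, and the highest other gave 27. In all 4 the real count was reached by at most 2 of the 100 splits. The types are clusters made to differ in expression, so the real split was favoured in advance and no conclusion on chance is drawn. These counts come from fits of 1 pair of types, where CD8 T cells gave 20 calls against 8 in the main fit. Of the 32 splits that part all 6 pairs of libraries only the real one gave any call (highest other 0); the splits with many calls part fewer pairs.

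Class II UMIs in CD8 T and NK cells were weighed first. Free RNA and doublets would keep the DP to DRA ratio of their source, but in NK cells that ratio exceeded that of barcodes under the filter by 3.24 (SD 1.37) and the highest of the class II-rich types by 3.23 (SD 1.27), above 0 in 6 of 6 animals. These types were B, classical monocyte, non-classical monocyte and myeloid dendritic cells. Doublets with plasmacytoid dendritic cells, which held 1.76% class II UMIs in cynomolgus 4, were not tested. NK cells of cynomolgus 1 and 3 held only 2 and 3 DP UMIs, and their barcodes under the filter 6 and 5, so over all 6 animals free RNA and doublets cannot be told apart from own expression. In the 4 animals with at least 20 DP UMIs in the barcodes under the filter, the NK differences were 3.80 (SD 1.35) and 3.73 (SD 1.17), and the lower 95% bounds of counting error were at least 1.95 and 2.39. This argues against free RNA, or doublets with the class II-rich types compared, as the whole source of the DP counts in NK cells of these 4. In rhesus 2, however, 2858 of the 3975 DP UMIs in NK cells were of DPB1*15:01, for which reads of another transcript stay open. That limit was set after the ratios were seen, first on the tested cells and then, since their DP UMIs enter the ratio, on the barcodes under the filter; both keep the same animals. DP UMIs per NK cell were above those per barcode under the filter in rhesus 1, rhesus 2 and cynomolgus 4, and about level in cynomolgus 2 (0.475 and 0.462). For CD8 T cells the differences over 6 animals, 2.19 (SD 1.75) and 2.18 (SD 1.67), fell to 0.19 and -0.27 in the lowest. In the same 4 animals they were 2.88 (SD 1.71) and 2.81 (SD 1.46), but the lowest bounds, 0.78 and 0.95, did not reach the limit of 1. DP UMIs per CD8 T cell lay under the background in cynomolgus 2 (0.418 and 0.462) and rhesus 1 (0.282 and 0.352). They lay above it in cynomolgus 4 (0.857 and 0.169) and rhesus 2 (2.13 and 0.293). Over all 6 and over these 4 animals, free RNA and doublets therefore cannot be told apart from own expression in CD8 T cells. A bound stayed under the limit in cynomolgus 2 (0.95) and rhesus 1 (0.78). In cynomolgus 4 and rhesus 2, singled out after the values were seen, both bounds were at least 3.6. This argues against free RNA, or doublets with the class II-rich types compared, as the whole source of the DP counts in CD8 T cells there. In rhesus 2, 1488 of the 2051 DP UMIs were of DPB1*15:01, for which reads of another transcript stay open. DRA is different: its UMIs per cell exceeded those per barcode under the filter in 0 animals for NK and 0 for CD8 T cells, as free RNA would give. That background also holds low-count cells, which may raise its DRA, so this does not settle the source. No biological explanation was tested.

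The tilt between class II alleles in NK cells of the rhesus animals was weighed next. It was not particular to NK cells. DPB1*07:01 took 9.40% of its pair in CD4 T and 15.2% in CD8 T cells of rhesus 2. DQB1*18:01:01:01 took 3.07% of its pair in CD4 T and 7.39% in CD8 T cells of rhesus 1. Free RNA would carry the allele shares of barcodes under the filter, but DPB1*07:01 took 15.4% in NK cells of rhesus 2 against at least 41.4% there, and DQB1*18:01:01:01 took 1.26% in NK cells of rhesus 1 against at least 19.5%, which argues against it as the source. The CD4 T and CD8 T shares, with their intervals, lie under the same bounds, so the same argument holds for their DPB1 and DQB1 counts. The class II level of CD4 T cells nevertheless lay at or under that background in 6 of 6 animals. Reads of another transcript counted to DPB1*15:01 stay open. NK cells with a UMI of DPB1*15:01 had 1.30 times the depth-scaled DPA1 level of those without (1336 and 423 cells), which lies between what a misassigned transcript and true co-expression would give. DRA was 0.852 times as high in them (11.6 and 13.6 CPM). In CD8 T cells the DPA1 level was 2.35 times as high (656 and 305 cells), but DRA was 4.97 times as high there, so that this could come from cells richer in class II as a whole. For DQB1*18:02:01:01 of rhesus 1, reads of another transcript were not tested and stay open as well. In CD4 T cells it held 411 UMIs, against 10 and 5 of the 2 DQA1 alleles. In B cells it held 6713, against 1884 and 2335. Each genotype was read in 1 animal, so that an allele's own regulation remains untested.

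The lower class I level in classical monocytes was also weighed. With TMM scaling, which counters a few genes taking most of the counts, the difference was -0.31 and did not pass (exact adjusted p 0.179), so that this explanation cannot be excluded. Reads lost between paralogs in the cynomolgus tables may add to it: the fall was -0.76 (SD 0.39) in the 4 cynomolgus animals and smaller by 0.56 in the 2 rhesus animals (exact p 0.267, smallest possible 0.0667), and species, batch and annotation cannot be told apart. Without the alleles at least 10 times higher in classical monocytes than in the 4 lymphocyte types, the rhesus mean was -0.47. Those alleles were picked for being high in monocytes, so this fall is set by the choice and decides nothing. With no depth scaling the mean did not fall: classical monocytes held 101 class I UMIs per cell and CD4 T cells 67.4. Whether the level is lower in the cells themselves depends on the scaling and remains open.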

How the results depend on the processing

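Alternatives with no mitochondrial filter, the automatic doublet threshold, a naming lead of 0.5 and no unnamed class I features were chosen after seeing the data; the rest were planned. Class II in B cells, NK cells and classical monocytes and class I in NK cells kept their direction and passed under every alternative run on 6 animals. Of the 4580 class II UMIs in NK cells of rhesus 2, 2858 were of DPB1*15:01, where reads of another transcript stay open. In NK cells of rhesus 1, 783 of 2201 were of DQB1*18:02:01:01, where such reads were not tested. The composition values moved by less than the spread between animals in 60 of 60 cases. Of the named genes 1613 values stayed on their side of the threshold, 51 no longer passed, 3 newly passed and 1 changed sign: MAMU-DOB in classical monocytes, 0.16 with the DESeq2 Wald test. Unless a construction is named, the cause was not tested.

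Class I in B cells no longer passed at 2000 UMIs (0.33, exact adjusted p 0.0625), with cells named by their own marker score (0.31, 0.125), with TMM (0.17, 0.25), with DESeq2 size factors (0.23, 0.156) and without the 18 unnamed features (0.16, 0.0625). Over this result's alternatives on 6 animals the adjusted p ran from 0.03125 to 0.25. Class I in classical monocytes no longer passed with TMM (-0.31, exact adjusted p 0.179) or DESeq2 size factors (-0.29, 0.156), and changed sign as mean UMIs per cell (0.29, 0.344), where monocytes hold more UMIs in all. Class II in CD8 T cells no longer passed at 2000 UMIs (2.01, 0.0625), with doublets kept (1.12, 0.188), at Leiden resolution 0.5 (2.20, 0.0625) or with the automatic doublet threshold (1.82, 0.0625). With no replicate block, that is without the pairing by animal, the same means lost their call for class I in B cells (0.35, exact adjusted p 0.121), CD8 T cells (0.48, 0.147) and classical monocytes (-0.57, 0.129) and for class II in CD8 T cells (1.91, 0.0900).

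Leaving out 1 animal leaves 5, where the smallest exact p is 0.0625 and no call can pass. The mean differences then ran from 0.27 to 0.42 for class I in B cells, 0.40 to 0.55 in CD8 T cells, 0.81 to 0.92 in NK cells and -0.67 to -0.48 in classical monocytes. For class II they ran from 8.21 to 8.76, 1.80 to 2.26, 2.02 to 2.54 and 7.39 to 7.81 in the same order. The list gene counts ran from 46 to 52, 6 to 10, 32 to 43 and 56 to 60. In CD8 T cells the 8 called genes became 5 without the replicate block, 20 in a fit of that pair of types alone and 13 with the DESeq2 Wald test. Camera with an estimated correlation gave adjusted p of 0.108 for costimulation in B cells, 0.913 for the class I pathway in CD8 T cells and 0.322 for handling stress in classical monocytes.

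The A share difference of CD8 T cells became 0.474 percentage points with cells named by their own marker score. B*048:01:01:01 took 27.8% with doublets kept and 27.5% as a mean over cells, and A1*019:11:01:01 16.7 and 16.3%. As a mean over cells, DQA1*23:01:01:01 took 54.5%, DQB1*18:01:01:01 21.1%, DRB*W004:01:01:01 50.6%, DPA1*02:01:01:01 59.5%, DPB1*07:01 36.9%, DQA1*01:04:01:01 80.1% and DQB1*06:01:01:01 67.5%, the last 64.9% with doublets kept. Both alleles were found more often at greater depth, by construction. Unthinned and at 3000 UMIs, the shares of B cells with both were 74.7 and 26.5% for DQA1, 90.5 and 57.5% for DQB1 and 100 and 97.7% for DRB in rhesus 1. In rhesus 2 they were 87.6 and 55.4% for DPA1, 98.7 and 87.8% for DPB1, 89.3 and 61.3% for DQA1 and 92.5 and 66.2% for DQB1, and for A1 in CD4 T cells 99.3 and 92.9%.

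Between species, leaving out the 18 unnamed features, which only the cynomolgus tables hold, moved class I to 1.13 in CD4 T, 1.13 in B, 0.88 in CD8 T, 0.89 in NK and 2.23 in classical monocytes, and CPM of shared genes moved class II in B cells to 0.41. The class II differences of CD8 T and CD4 T cells, 0.90 and 0.57, changed sign to -0.12 and -0.15 without rhesus 2, and that of CD8 T cells to -0.23 without cynomolgus 3. Class I in CD4 T cells (0.10) became -0.09 without cynomolgus 3 and -0.04 without rhesus 2, in CD8 T cells (-0.16) 0.13 without cynomolgus 4 and 0.11 without rhesus 1, and in NK cells (-0.07) 0.09 and 0.05 without the same 2 animals and 0.06 as CPM of shared genes. Class I in classical monocytes was 0.38 without cynomolgus 3. Background subtraction was not run for class II, since CD4 T cells lay at or under the background in 6 of 6 animals. The A share and allele results were not run in the cynomolgus animals, cynomolgus 3 included. Depth limits class II in CD4 T cells, with 0.315 UMIs per cell, and CIITA, with 12 UMIs in all of them.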

Other observations

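The tests on the A share were chosen after the allele values were seen, and the search of the cynomolgus tables before its result was seen.

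Without the alleles at least 10 times higher in classical monocytes than in the 4 lymphocyte types, the A share was 36.0% in rhesus 1 and 41.7% in rhesus 2, and the mean difference to CD4 T cells became 3.77 percentage points in place of -4.44. The alleles left out are all of the B locus and were picked for being high in monocytes, so the rise is set by the choice, and whether they cause the lower A share cannot be told.

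A counterpart of these alleles was sought in the cynomolgus tables. The number of class I features at least 10 times higher in classical monocytes in all 4 cynomolgus animals was 0, but the feature LOC106996627, 1 of the 18 unnamed, met the rule in cynomolgus 1, with 3517 CPM in classical monocytes against 37.5 CPM in CD4 T, 60.5 CPM in B, 57.9 CPM in CD8 T and 71.1 CPM in NK cells. In cynomolgus 2, 3 and 4 it stood at 123, 60.8 and 70.1 CPM in classical monocytes and at 502, 96.6 and 120 CPM in CD4 T cells. Genotypes that lack such a gene and reads counted elsewhere cannot be told apart.

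Plasmacytoid dendritic cells, with 108, 75 and 88 cells in cynomolgus 1, 3 and 4, held 1.61% class II UMIs (SD 0.861).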
